A study of Mus musculus with 4 samples.

How the data were processed

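RNA described by the labels as cytoplasmic was taken from mouse embryonic stem cells after 0, 2, 4 and 6 h with actinomycin D, 1 library per time. Ribosomal RNA was depleted and directional libraries were made, per the labels' protocols. Reads were aligned with STAR 2.5.3a to mm10 and counted with featureCounts of Subread 1.6.3, per the submitters' processing notes. The annotation release, strand setting and handling of multi-mapping reads are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart.

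The deposited table has 41328 rows of raw counts. The authors also deposited a ratio, each count divided by 1 whole number per library (8778, 4259, 4961 and 3413), whose meaning is not stated, and a half-life in hours with the fraction of variance explained by its line (R2). Refitting a line through the natural log of the authors' ratio gave the deposited half-lives to within a relative 3.4e-10. They are given for 17413 rows with a count above 0 in all 4 libraries. R2 was 0.8 or more in 8850 of them (50.8%).

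Counts as deposited were used for all tests. Totals were 90833314, 38510903, 39189022 and 26479671, and 3 counts, the floor for a count of 0, correspond to 0.032, 0.0764, 0.0781 and 0.12 CPM. Rows above 0 numbered 21374, 19631, 19835 and 19959, and the 10 most abundant genes took 10.5 to 12.0% of counts. The 3 rows named BGIVT, FLIVT and RLIVT are not mouse gene symbols and the labels do not describe them. They held 0.478, 0.525, 0.633 and 0.734% of counts and stayed out of library sizes and tests. Genes with 10 counts in at least 1 library and a mean of 1 CPM were kept, 12106 in all.

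A linear time term was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, 2 residual and 4.89 prior degrees of freedom) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Standard errors of slopes came from limma 3.58.1 (trend) on log2 CPM with an offset of 0.5 counts. Curvature used an added quadratic term. Gene lists were described by their median slope, its percentile among 10000 random lists matched in 20 expression bins, the calls among members, fry, and camera with a correlation of 0.01 or an estimated one. Fry asks whether members move one way on balance (directional) or at all (mixed) and compares with no other genes. With an estimated correlation camera rests on the 2 residual degrees of freedom and has little power, so failing it says little about a list. Half-life was -1 divided by the slope minus the median slope of ribosomal protein mRNAs, 0.096. Folds of single libraries carry an exact conditional binomial 95% interval, which covers counting error only.

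Groups, tests, lists and the alternatives, save those said to be added later, were fixed before the data were examined. Named genes were the 12 steepest falling and 8 steepest rising genes moving one way at every step with 10 CPM at 0 h (falling) or 6 h (rising), leaving out predicted, clone, small RNA and pseudogene names by pattern, up to 2 called members per direction of each list, and 18 fixed genes. The pattern did not catch the clone names starting RP23 and RP24. Of 114 named genes measured, 59 fell, 54 rose and 1 was not called. The values of some of them are not reported here. Gene positions and features came from GENCODE M21 (GRCm38, the mm10 build), where 11200 of the 12106 symbols (92.5%) matched 1 gene.

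The fit was tested on simulated counts for 12106 genes. It called 50 of 50 genes with a slope of -0.5, 42 of 50 with -0.2, 11 of 50 with -0.1 and 19 of 50 with 0.1, and 2 of 11906 unchanged genes. The simulated genes were independent, lay about straight lines and took their dispersion from the same fit. The simulation therefore says nothing about curved courses or shifts shared by many genes of 1 library. Alternatives were other scalings (DESeq2 1.42.0 size factors, library size, upper quartile, ribosomal protein or respiratory chain mRNAs), 2 other count filters, robust quasi-likelihood, DESeq2's Wald test, limma-voom, each library left out, and mitochondrial and small RNA genes left out. A fit without 1 library has fewer residual degrees of freedom, so a call lost there need not rest on that library. Scaling by the IVT rows and thinning to the smallest library were added after the data were seen. Features were computed with python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.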

Results

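Mouse embryonic stem cells were exposed to actinomycin D, an intercalating drug that blocks RNA synthesis, and RNA was sequenced after 0, 2, 4 and 6 h. The cells were of the E14-NKX2-5-EmGFP line, moved from feeder cells to gelatin before the drug was given. The labels describe the material as cytoplasmic RNA. Each time point was 1 library, so the series held 4 libraries and no replicates, and the drug was at 10 µg/ml in the 3 treated ones. The design text names transcriptome-wide mRNA half-lives as the aim. Total counts were 90833314 at 0 h, 38510903 at 2 h, 39189022 at 4 h and 26479671 at 6 h. The p-values below measure the scatter of 4 single libraries about a straight line in time, not the spread between cultures.

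Loss of RNA was uneven across genes. Of 12106 genes tested, 3497 fell and 2542 rose relative to the typical transcript over the 6 h, and 6067 passed neither way (edgeR quasi-likelihood test of a linear time term, Benjamini-Hochberg adjusted p under 0.05). Most measured histone, zinc finger and immediate early transcripts fell, while most transcripts for ribosomal proteins and the respiratory chain gained share. The median slope was -0.18 log2 units per hour among falling genes and 0.077 among rising genes. At least 0.25 log2 units per hour was lost by 1106 of the falling genes. Of the falling genes 2877 went down at every step, and 1908 rising genes went up at every step. Of all 12106 tested genes 3226 went down and 2526 went up at every step, where random orders of 4 values give 4.17% for each direction. Because the counts give shares of a pool, "rose" means lost more slowly than the typical transcript or truly increased. With the ribosomal protein mRNAs setting the scale the median slope of all genes moved from 0.0017 to -0.094, and the calls became 7766 falling and 63 rising. Rising genes made up 42.1% of calls on the main scale and 0.805% on that one, 22.8% with library size alone and 1.01% with respiratory chain mRNAs as reference. Scaling by the 3 entries named IVT, tried after the data were seen, moved the median slope to -0.125 and left 0.714% of calls rising. Without the 0 h library 2049 genes fell and 699 rose. Of the gene lists 9 passed the directional fry test with all 4 libraries. None of them did without the 0, 2 or 6 h library, and without the 4 h library only S phase genes did (adjusted p = 0.00462). Fits without 1 library had fewer residual degrees of freedom, so these losses do not show that a list rests on that library.

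The steepest falls by the rule for named genes were mostly in histone and zinc finger genes. Hist1h1d, a linker histone gene (chromosome 13, 23553262 to 23560686 in GRCm38), went from 609 CPM (library-size-scaled counts, with TMM factors) at 0 h to 17.6 at 6 h. Its 6 h level was 0.0289 of the 0 h level (95% interval 0.0262 to 0.0317, counting error only). The other histone genes of this group were Hist1h4j, with a slope of -0.81 ± 0.13 (SE), and Hist1h2bc, with -0.73 ± 0.11. The zinc finger genes Zfp87, Zfp748, Zfp707, Zfp472, Zfp39 and Zfp51 had slopes of -0.88, -0.84, -0.82, -0.78, -0.75 and -0.73 log2 units per hour. Nodal, a TGF-beta family ligand, fell from 81.5 to 4.79 CPM, Aunip from 42.7 to 2.67 and the clone-named gene RP24-548A15.1 from 12.7 to 0.837. The calls of Hist1h1d, Hist1h4j, Hist1h2bc and Zfp748 were lost with the robust form of the test (adjusted p = 0.0996, 0.0909, 0.0609 and 0.0655).

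Gains were smaller. RP23-478A9.4 went from 2.19 to 12.9 CPM, the mitochondrial 16S ribosomal RNA mt-Rnr2 from 245 to 1006 and the nuclear RNA Malat1 from 1535 to 5202. For Malat1 most of the change came before 2 h, when it stood at 4717. Its call (slope 0.26 ± 0.075, edgeR adjusted p = 0.0417) was lost with the robust test (adjusted p = 0.288), with library size (0.0623), with DESeq2 (0.0569), with the stricter count minimum (0.0529), without the 4 h library (0.0756) and without the 0 h library (slope 0.040, adjusted p = 0.26). The calls of mt-Rnr2 and RP23-478A9.4 were also lost with the robust test, at adjusted p = 0.128 and 0.0908. Jun, a component of AP-1, rose from 4.96 to 11.8 CPM, and the snoRNA hosts Snhg14 and Snhg4 reached 2.18 and 2.04 times their 0 h level, the Snhg14 call being lost without the 0 h library (adjusted p = 0.15). Terc, the telomerase RNA, and Tpt1 reached 2.04 and 1.86 times. Of the 54 named rising genes, 8 were still called rising with ribosomal protein mRNAs as reference and 10 with respiratory chain mRNAs, and 32 kept a slope above 0 with ribosomal protein mRNAs as reference 41 with respiratory chain mRNAs and 14 with the entries named IVT. RP23-478A9.4, mt-Rnr2, Jun, Snora23 and Snora81 were called rising under all 3 references. The reads of mt-Rnr2, a ribosomal RNA, are those left after ribosomal RNA was depleted. Differences in depletion between libraries were not tested.

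**Figure D1:**
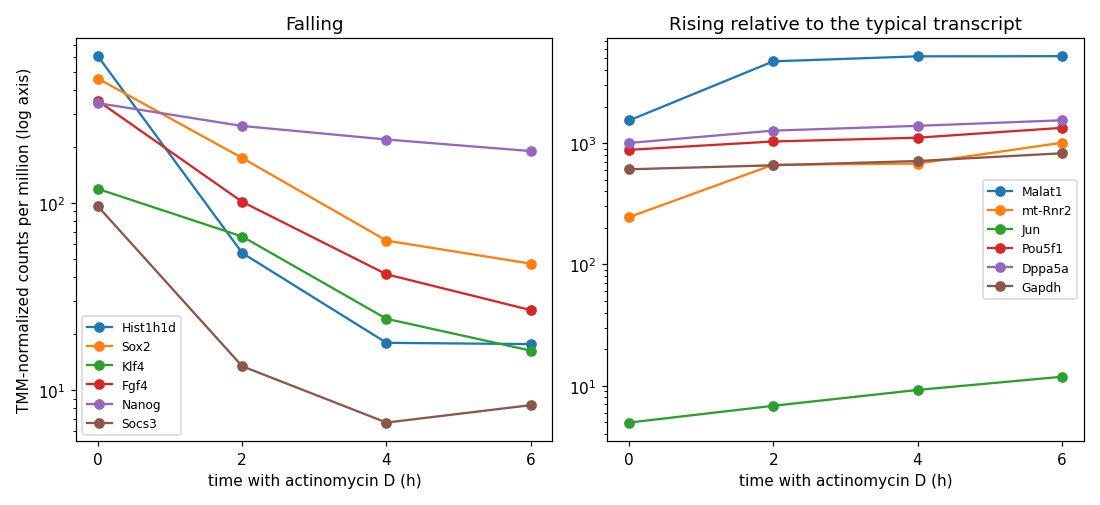
TMM-normalized CPM (log axis) against hours with actinomycin D for 12 of the named genes, 1 library per point with no error bars. Hist1h1d falls from 609 to 17.6 and Socs3 from 95.9 to 8.29, while Malat1 climbs from 1535 to 4717 by 2 h; the slope of Gapdh goes below 0 with ribosomal protein, respiratory chain or IVT entries as reference, and those of Pou5f1 and Dppa5a with the IVT entries.

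Pluripotency transcripts differed widely in slope. Of 36 measured, 22 fell and 8 rose, with a median slope of -0.13. When the 0 h library was left out, 17 fell and 3 rose, without the 2 h library 5 rose, and with library size 3 rose. The median lay below those of all 10000 expression-matched random lists. Fgf4, a growth factor, fell from 351 to 26.7 CPM, and Sox2 (chromosome 3, 34650405 to 34652461) from 462 to 47.3. Klf2, Klf4 and Zfp42 had 0.112, 0.137 and 0.306 of their 0 h level at 6 h. Nanog fell to 0.554 and Esrrb to 0.78, the latter not called without the 0 h library (adjusted p = 0.249). Pou5f1, which encodes Oct4, went from 879 to 1335 CPM and Dppa5a from 1002 to 1541, and with ribosomal protein mRNAs as reference neither passed (adjusted p = 0.969 and 0.756), while both slopes were below 0 (-0.032 and -0.028) with the 3 entries named IVT as reference. Adjusted over the list alone, 22 fell and 9 rose. The directional fry test gave adjusted p = 0.0676 and the mixed test 0.0349, and camera with an estimated correlation gave adjusted p = 0.424.

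Most immediate early and feedback transcripts fell. Among immediate early genes 29 of 38 fell, 8 were not called and 1 rose (29 falling and 2 rising adjusted over the list alone), and the robust test kept 22 falling. Hes1, a Notch target, fell to 0.0917 of its 0 h level and Csrnp1 to 0.115, while Jun was the riser. Fos had 2.66, 3.29, 1.95 and 1.87 CPM and no call (adjusted p = 0.15), but was called falling with ribosomal protein or respiratory chain mRNAs as reference (slopes -0.20 and -0.19, adjusted p = 0.0145 and 0.0249). Myc was below the filter, with 1.00, 0.662, 0.521 and 0.917 CPM (94, 26, 20 and 23 counts). Of the BMP, LIF and FGF feedback targets 22 of 25 fell and 1 rose (22 and 2 over the list alone). Socs3, a LIF-induced inhibitor of JAK signalling, fell from 95.9 to 13.4 by 2 h. Id1 and Id3, BMP targets, had slopes of -0.17 and -0.10. Id1 was not called without the 0 h library (slope -0.040, adjusted p = 0.801), without the 4 or 6 h library (0.0739 and 0.0542) or with DESeq2 (0.184), and Id3 was not called without the 2 or 6 h library (0.0556 and 0.11). Lefty2, a TGF-beta family inhibitor, had a slope of 0.049 that became -0.046 with ribosomal protein mRNAs as reference and was below 0 with the other 2 references. Its call was lost with library size (adjusted p = 0.159) and without the 0 or 2 h library (0.123 and 0.0647). Of 27 p53 targets 17 fell and none rose, over all genes and over the list alone. Gdf15, Cdkn1a and Mdm2 fell to 0.099, 0.175 and 0.328. Directional fry gave adjusted p = 0.0761, 0.0676 and 0.0519 for these 3 lists, and camera with an estimated correlation 0.425, 0.424 and 0.424. The calls of Hes1, Csrnp1, Socs3, Gdf15 and Cdkn1a were lost with the robust test (adjusted p = 0.0857, 0.11, 0.135, 0.134 and 0.0936), and that of Gdf15 also with DESeq2 (0.0623). With the 0 h library left out, Csrnp1 and Gdf15 had slopes of -0.15 and -0.087 and no call, and 19 immediate early genes and 11 p53 targets fell.

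All 56 measured replication-dependent histone genes fell, with a median slope of -0.63, and 56 did so adjusted over the list alone. Hist1h3h went from 82.9 CPM at 0 h to 7.46, 2.21 and 2.99, and Hist1h3g from 166 to 12.9, 4.38 and 5.78. The course was far from straight, and the robust test kept 5 of the 56 calls (adjusted p = 0.0987 and 0.117 for these 2 genes). DESeq2 called 54 and limma-voom 56, and the median stayed below 0 under each scaling. With the 0 h library left out, 49 fell and the median slope was -0.28, and without the 6 h library it was -0.95. The fry tests did not pass (adjusted p = 0.145 directional, 0.123 mixed; camera adjusted p = 0.442 with an estimated correlation). Many histone genes are near-identical copies, so the count of a single one is uncertain.

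KRAB and C2H2 zinc finger genes, mostly DNA-binding repressors, were the largest falling group, with 294 of 355 falling and 3 rising (305 and 5 adjusted over the list alone) and a median slope of -0.25. Zfp664 and Zfp277 had slopes of 0.076 and 0.065, both below 0 with ribosomal protein mRNAs, respiratory chain mRNAs or the IVT entries as reference. Without the 0 h library 181 of the group fell and 1 rose, and neither of these 2 genes was called (adjusted p = 0.146 and 0.532). Zfp277 was also not called with library size (adjusted p = 0.166) or without the 2 or 4 h library (0.0537 and 0.0674). Directional fry gave adjusted p = 0.0789, mixed 0.0497, and camera with an estimated correlation 0.424.

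Transcripts of the translation and energy machinery gained share together. All 78 cytoplasmic ribosomal protein mRNAs rose, with a median slope of 0.096 (-0.032 with the IVT entries as reference), as did 71 of 76 nuclear-encoded respiratory chain mRNAs, with 0.088 (-0.040 on that reference), and the counts were the same adjusted over the list alone. Rps27a reached 1.63 and Rpl24 1.45 times the 0 h level, both below 0 in slope with the IVT entries as reference, and the Rpl24 call was lost with the robust test (adjusted p = 0.169), without the 0 h library (0.121), with library size (0.0893), with DESeq2 size factors (0.0507) and with the stricter count minimum (0.061). Cox7b and Cox6c, complex IV subunit genes, reached 1.61 and 1.57 times, below 0 in slope with the IVT entries as reference. Both lists passed directional fry (adjusted p = 0.0271 and 0.0406). Neither passed camera with an estimated correlation (adjusted p = 0.424 for each), a test with little power on 2 residual degrees of freedom. With ribosomal protein mRNAs as reference the respiratory chain median was -0.0068, and under any of the 3 references none of the 78 ribosomal protein mRNAs was called rising. When the 0 h library was left out, 63 of the 78 and 40 of the 76 rose.

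In glycolysis and the proteasome more genes rose than fell relative to the typical transcript, and each median went below 0 with ribosomal protein mRNAs, respiratory chain mRNAs or the IVT entries as reference. The 2 medians lay at percentiles 90.6 and 99.6 of expression-matched random lists, so the glycolysis list was not far from equally abundant genes. In glycolysis 14 of 20 rose and 3 fell, over all genes and adjusted over the list alone, with a median slope of 0.068 (-0.027 with ribosomal protein mRNAs as reference). Pgk1 and Ldhb, glycolytic enzymes, had slopes of 0.095 and 0.094, both below 0 with ribosomal protein mRNAs or the IVT entries as reference, while the transporters Slc2a1 and Slc16a3 fell to 0.481 and 0.788. The list passed directional fry (adjusted p = 0.0189) and had adjusted p = 0.424 with an estimated correlation. The proteasome list had 30 of 40 rising and 1 falling (33 and 1 adjusted over the list alone), with a median of 0.067 (-0.028 with ribosomal protein mRNAs as reference). Psma8 and Psma7, proteasome subunits, stood at 1.52 and 1.53 times (below 0 in slope with the IVT entries as reference) and Psmd7 at 0.696. With the 0 h library left out, 9 glycolysis and 9 proteasome genes rose, and Slc16a3 and Psma8 were not called (adjusted p = 0.257 and 0.107). Slc16a3 was also not called without the 2 h library (adjusted p = 0.0742) or with upper-quartile scaling (0.0595). Without the 6 h library Psmd7 was not called (0.148), and with library size 10 glycolysis and 17 proteasome genes rose.

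More translation factor, aminoacyl-tRNA synthetase and secretory pathway genes rose than fell relative to the typical transcript, though none of these lists passed the directional fry test. Their medians lay at percentiles 71.5, 30.5 and 99.3 of expression-matched random lists. Translation factors and synthetases therefore moved much as equally abundant genes did. Among translation factors 23 of 37 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.059 (-0.036 with ribosomal protein mRNAs as reference). Pabpc1, the poly(A)-binding protein gene, and Eif3b reached 1.75 and 1.64 times (below 0 in slope with the IVT entries as reference), and Eif1a and Eif3a fell to 0.525 and 0.749. Of 18 synthetase genes 14 rose (15 adjusted over the list alone), with a median of 0.050 (-0.045 on that reference) and Dars and Gars at 1.46 and 1.32 times (both below 0 in slope with the IVT entries as reference). Of 24 genes of ER-made proteins 21 rose, with a median of 0.068 (-0.027 on that reference) and Sec61b and Ssr3 at 1.53 and 1.46 times (both below 0 in slope with the IVT entries as reference). Directional fry gave adjusted p = 0.0725 for the proteasome and 0.0519 for the other 3 lists, and camera with an estimated correlation gave adjusted p = 0.442 and 0.424. With the 0 h library left out, 10 translation factor, 2 synthetase and 8 ER genes rose, and Dars, Gars and Ssr3 were not called (adjusted p = 0.0711, 0.141 and 0.0645), nor Gars with library size (0.0611). Without the 2 h library 7 synthetase genes rose, and with library size 14, 2 and 10 genes of the 3 lists rose.

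Mitochondrial RNA went apart. Of 13 listed mRNAs encoded in the mitochondrion 7 were measured. The others, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l, had 0 counts in every library, and the reason was not tested. Of the 7 measured, 3 fell (4 over the list alone) and none rose. Among those falling were the complex I genes mt-Nd1 to 0.5 and mt-Nd2 to 0.52. Without the 6 h library 3 of the 7 rose. The mt-Nd2 call was lost with the robust test (adjusted p = 0.0558) and without the 0 h library (slope -0.016, adjusted p = 0.788). Of 24 listed mitochondrial rRNAs and tRNAs 2 were measured. Of these 1 rose, mt-Rnr2, a ribosomal RNA in libraries depleted of ribosomal RNA. Mitochondrial ribosomal protein mRNAs, made in the nucleus, had 16 of 75 falling and 18 rising (16 and 17 over the list alone), and 3, 12 and 28 rose without the 0, 2 and 6 h libraries and 7 with library size. Mrps31 and Mrpl44 fell to 0.274 and 0.354 and Mrpl13 and Mrpl42 rose to 1.57 and 1.52 times (below 0 in slope with the IVT entries as reference). Their median slope of 0.011 and mean of -0.011 differed in sign, the median was below 0 with library size, the 3 references, the stricter count minimum and without the 0 h library (-0.010, -0.084, -0.073, -0.12, -0.0012 and -0.015), and fry gave adjusted p = 0.126 for the first list and 0.52 for the last.

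Cell cycle transcripts were mixed. Among expression-matched random lists the S phase median lay at percentile 4.65, and the mitosis median lay below all 10000. Of 30 S phase genes 9 fell and 4 rose, and 0, 2, 2 and 12 rose without the 0, 2, 4 and 6 h libraries. Upper-quartile scaling gave 7 falling and 10 rising, library size 10 and 1, and ribosomal protein mRNAs as reference 27 and 0. Cdt1 and Chaf1a, a licensing factor and a chromatin assembly factor, fell to 0.162 and 0.249, and Gins2 had a slope of 0.062 that was below 0 with ribosomal protein mRNAs or the IVT entries as reference. The list's median slope was 0.014 (-0.0066 with library size, -0.081 with ribosomal protein mRNAs as reference), its mean -0.047 and its fry direction down (adjusted p = 0.027, and adjusted p = 0.778 with an estimated correlation). Of 30 mitosis genes 17 fell and 2 rose (11 and 0 without the 0 h library, 14 and 4 without the 6 h library, 13 and 4 with upper-quartile scaling), with Sgol1 and Aurka at 0.171 and 0.329 and Cenpa and Ccnb2 at 1.45 and 1.31 times, their slopes below 0 with ribosomal protein mRNAs or the IVT entries as reference (fry adjusted p = 0.0189, and adjusted p = 0.424 with an estimated correlation). Of 9 D-type cyclins and inhibitors 4 fell and 3 rose, with Cdkn1a and Cdkn2d falling and Cdkn2a and Ccnd1 with slopes of 0.13 and 0.063, the latter below 0 with any of the 3 references. The list's median was -0.039 (0.044 with the stricter count minimum) and fry gave adjusted p = 0.177. For RNA decay factors 21 of 56 fell and 9 rose (22 and 12 over the list alone), 14 and 2 without the 0 h library 22 and 14 without the 6 h library and 19 and 16 with upper-quartile scaling, with Exosc4 and Zfp36l2 at 0.238 and 0.276 and Smg5 and Cnot10 at 1.48 and 1.42 times, below 0 with ribosomal protein mRNAs or the IVT entries as reference. The list's median was -0.012 and 0.0046 with upper-quartile scaling (fry adjusted p = 0.0339, and adjusted p = 0.424 with an estimated correlation). Gins2, Cenpa, Ccnb2 and Cnot10 were not called without the 0 h library (adjusted p = 0.105, 0.0831, 0.15 and 0.0884), nor Gins2, Ccnb2 and Ccnd1 with library size (0.0697, 0.0735 and 0.0597).

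Non-coding RNAs that were measured mostly rose or held no call. Of 147 listed small nucleolar and Cajal body RNAs, guides of RNA modification, 34 were measured and the rest were below the filter. Of the 34, 31 rose, with a median slope of 0.15 and Snora23 and Snora81 at 4.09 and 3.11 times (fry adjusted p = 0.0828). Without the 0 h library 10 of the 34 rose, with library size 18 and with the robust test 22. With ribosomal protein mRNAs as reference 9 rose and 1 fell, and with respiratory chain mRNAs 10 rose. The list of RNA polymerase III and abundant small RNAs had 4 of 7 rising, with a median of 0.049 that went below 0 (-0.047) with ribosomal protein mRNAs as reference. Terc and the RNase MRP RNA Rmrp were in this list, the latter at 1.79 times (fry adjusted p = 0.027, and adjusted p = 0.424 with an estimated correlation). Of 16 snoRNA host genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.066 that went below 0 (-0.029) on the same reference. Snhg11 stood at 2.38 times and Snhg5 at 0.431, and the Snhg5 call was lost with the robust test (adjusted p = 0.0589). The host list passed fry (adjusted p = 0.0189) and had adjusted p = 0.424 with an estimated correlation. Of 11 nuclear-retained RNAs 3 fell and 3 rose, with a median of 0.032 (-0.064 with ribosomal protein mRNAs as reference), a mean of -0.030 and fry adjusted p = 0.409. When the 0 h library was left out, 1 of them fell and none rose. Mir17hg and Mirg, host genes of microRNAs, fell to 0.197 and 0.318 and Meg3 reached 2.2 times, and the Mir17hg call was lost with the robust test (adjusted p = 0.0751). Snhg5, Snhg11, Mir17hg and Meg3 were not called without the 0 h library (adjusted p = 0.168, 0.0895, 0.147 and 0.0523), and without the 6 h library 3 snoRNA host genes fell.

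Markers of other cell types differed from list to list, and many were below the filter. Measured were 8 of 32 fibroblast, 9 of 19 primitive endoderm, 8 of 14 trophectoderm, 5 of 15 neural and 1 of 16 mesoderm markers. Among those below it, Col1a1, Col1a2, Gata6, Cdx2 and Elf5 had 10, 7, 15, 2 and 6 counts at 0 h. The measured members need not come from other cell types, and this was not tested. Of 8 measured fibroblast markers 2 rose (1 adjusted over the list alone), with a median slope of 0.043 that went below 0 (-0.053) with ribosomal protein mRNAs as reference. Thy1, a surface glycoprotein gene, had 2.94 CPM at 0 h and a slope of 0.10 (below 0 with the IVT entries as reference), and Sparc a slope of 0.071 (below 0 with any of the 3 references). Of 9 primitive endoderm markers Gata4 fell and Sparc rose, the median being -0.0030 and 0.051 without the 0 h library. Of 8 trophectoderm markers 4 fell and 2 rose, with a median of -0.11 (0.0037 with the stricter count minimum). The transcription factor genes Ascl2 and Tfap2c stood at 0.19 and 0.335, and the keratin genes Krt7 and Krt8 had slopes of 0.088 and 0.086, below 0 with ribosomal protein mRNAs or the IVT entries as reference. Of 5 neural markers 3 fell, with a median of -0.050 and Otx2 and Pou3f1 at 0.192 and 0.44. The 1 measured mesoderm marker had a slope of 0.080 and no call, and Eif1a, with a slope of -0.15, was the 1 measured member of the 2-cell list. Fry gave adjusted p = 0.0519, 0.927, 0.0676 and 0.126 for fibroblast, primitive endoderm, trophectoderm and neural markers. Thy1 and Krt7 were not called when any 1 library was left out (adjusted p = 0.0595 to 0.282 and 0.0725 to 0.099), with library size (0.0934 and 0.0846), without a count minimum (0.0673 and 0.0528) or with DESeq2 (0.161 and 0.0722). With the 0 h library left out, 2 trophectoderm and 0 neural markers fell, and Gata4, Ascl2, Krt8, Otx2 and Pou3f1 were not called (adjusted p = 0.0633, 0.059, 0.0513, 0.181 and 0.234).

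Stress, sterol and housekeeping genes were split. Cholesterol genes had 5 of 22 falling and 10 rising, with a median slope of 0.041 (-0.054 with ribosomal protein mRNAs as reference), a mean of -0.0026 and fry adjusted p = 0.126. With the 0 h library left out, 3 fell and 3 rose, without the 2 h library 3 and 4, without the 4 h library 3 and 8, and with library size 5 and 2. Sqle, which encodes squalene epoxidase, fell to 0.517, and Tm7sf2 and Dhcr7 stood at 1.34 and 1.38 times, below 0 in slope with any of the 3 references. Heat shock and unfolded protein genes had 12 of 24 falling and 8 rising, with a median of -0.025 that was 0.025 with the stricter count minimum and 0.0028 without the 0 h library. Chac1 and Atf3, targets of the stress response, fell to 0.0663 and 0.177, and the Chac1 call was lost with the robust test (adjusted p = 0.128) and without the 0 h library (slope -0.17, adjusted p = 0.199). The chaperone genes Hsp90ab1 and Hspe1 stood at 1.49 and 1.37 times, below 0 in slope with ribosomal protein mRNAs or the IVT entries as reference. Without the 0 h library 9 of the list fell and 2 rose, and Tm7sf2 and Hspe1 were not called (adjusted p = 0.0829 and 0.129). This list passed fry (adjusted p = 0.0406, down) and had adjusted p = 0.424 with an estimated correlation. Of 16 housekeeping genes 12 rose and 2 fell, with a median of 0.076 (-0.019 with ribosomal protein mRNAs as reference) and fry adjusted p = 0.0519. When the 0 h library was left out, or with library size, 7 rose. Tbp, the TATA-binding protein gene, fell to 0.524, while Ywhaz and Rplp0 stood at 1.48 and 1.52 times, below 0 in slope with the IVT entries as reference. Gapdh and Actb had slopes of 0.072 and 0.076 that became -0.023 and -0.019 with ribosomal protein mRNAs as reference and were below 0 with the other 2 references.

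**Figure D2:**
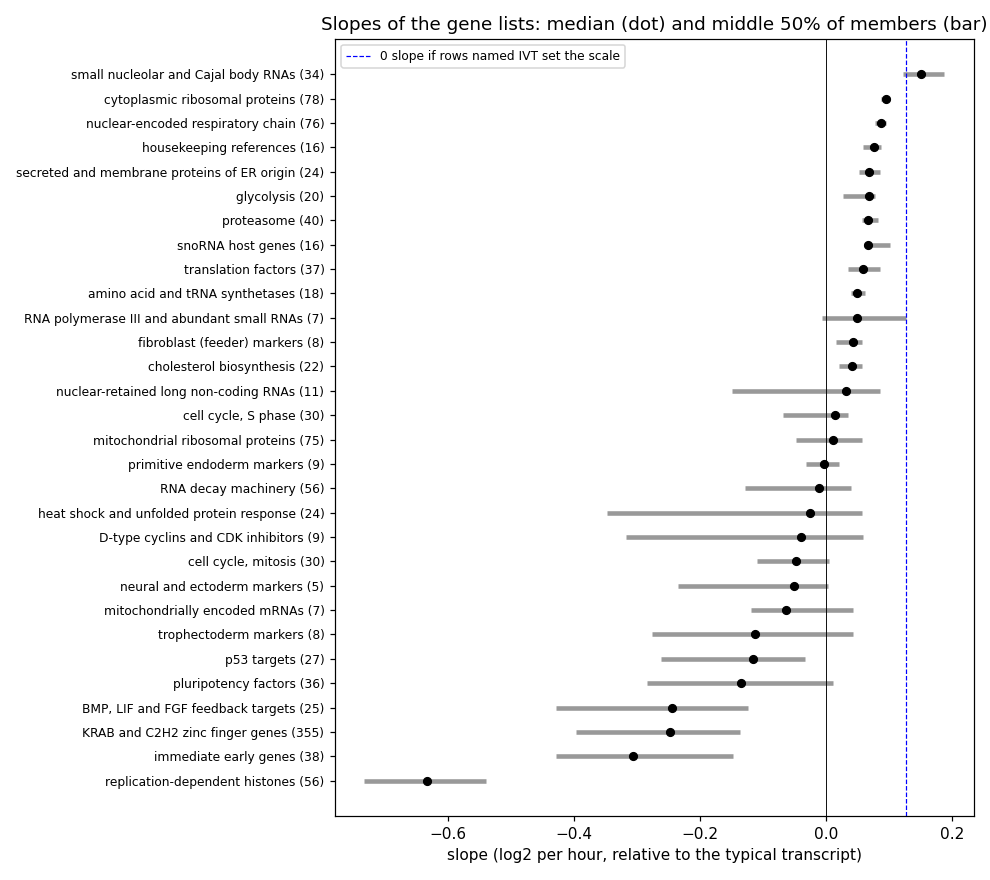
Slopes of the lists with 5 or more measured members, as median (dot) and middle 50% of members (bar), in log2 units per hour relative to the typical transcript, member number in brackets. Histones have the lowest median, -0.63, and the dashed line marks where 0 would lie if the 3 entries named IVT set the scale, with the ribosomal protein list at -0.032 on that scale.

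On the main scale loss slowed with time for many falling genes. Their median change was -0.43 log2 units from 0 to 2 h, -0.38 from 2 to 4 h and -0.22 from 4 to 6 h. Of 3497, 2553 lost more in the first interval than in the last. Over these intervals ribosomal protein mRNAs had median changes of 0.25, 0.16 and 0.16. The IVT entries stood at 4636, 5147, 6457 and 7748 CPM at 0, 2, 4 and 6 h. Against the IVT entries the median loss would be largest from 2 to 4 h, so the order of the intervals depends on the scale. A quadratic time term passed in 1202 genes, 745 bending upward and 457 downward (edgeR, adjusted p under 0.05, 1 residual degree of freedom). Among falling genes 612 bent upward and 37 downward. DESeq2 called 246 genes curved and the stricter count minimum 601. Folds of single libraries against 0 h put 535 genes at or below 0.5 after 2 h, 1422 after 4 h and 1908 after 6 h, and 72, 124 and 145 genes at or above 2. These pairs of libraries have no replicate check, and most of these counts moved with the reference and the count filter, as given below.

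Apparent half-lives were read against the ribosomal protein mRNAs, taken as stable. On that reference the typical gene had a half-life of 10.6 h. Under 2 h stood 406 genes, 3186 had 2 to 6 h, 2982 had 6 to 12 h, 2549 had 12 to 24 h and 2228 had 24 h or more. Another 755 genes did not fall against the reference. Sox2 had 1.51 h, Klf2 1.55 h, Klf4 1.66 h, Zfp42 2.6 h, Nanog 4.23 h and Esrrb 6.42 h. Values much beyond the 6 h window rest on small slopes. With library size as the reference the typical gene had 53 h. The 7 measured mitochondrially encoded mRNAs as reference gave it no half-life at all. Neither did the typical transcript, but that outcome was fixed in advance because the scaling sets its slope near 0. The authors' deposited table lists half-lives for 17413 rows, of which 2427 (13.9%) lie below 0, with a median of 8.96 h among those above 0. Across 11280 genes with values above 0 in both, the authors' deposited table and the recomputed half-lives had a Spearman rho of 0.999 across genes. Both are slopes of lines through the same 4 columns of counts and differ mainly by a scaling, so a rho near 1 follows from their construction and is no check of either.

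**Figure D3:**
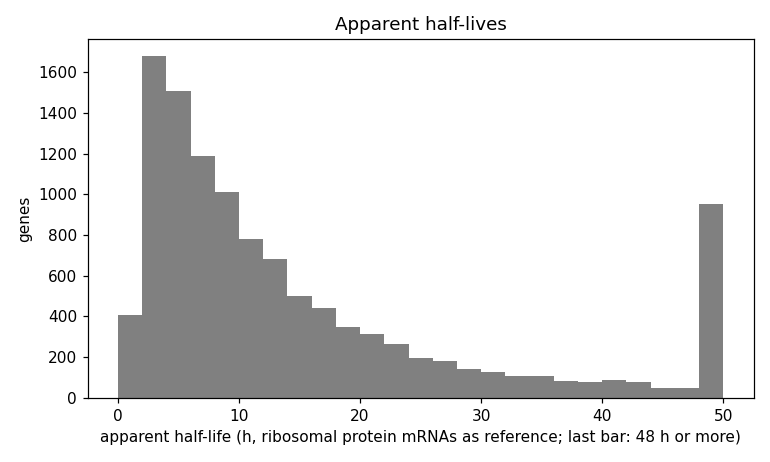
Number of genes against apparent half-life in hours, in bars of 2 h, with ribosomal protein mRNAs as reference and 48 h or more gathered in the last bar. Of 11351 genes with a half-life, 406 lie under 2 h and 2228 at 24 h or more.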

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

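All tests in this part were chosen only after the result was seen. The table holds 3 entries, BGIVT, FLIVT and RLIVT, that are not mouse genes and that the labels do not describe. At 6 h they stood at 95.3, 575 and 7080 CPM, and together they rose from 4636 at 0 h to 7748 at 6 h. Their names might stand for RNAs transcribed in vitro and added at a fixed amount per sample. If so, their rise would measure a shrinking RNA pool, and scaling by them gave 9454 falling and 68 rising genes and a half-life of 7.99 h for the typical gene. Their summed slope, 0.127 log2 units per hour, exceeded that of the ribosomal protein mRNAs by 0.032. Among the 3 entries FLIVT made up 7.38, 7.85, 8.68 and 7.42% of reads at 0, 2, 4 and 6 h, and with 1 library per time this was not tested against library noise. Whether they were added, when, and in what amount is not given in the sources used here.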

How the results depend on the processing

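The tests with the IVT entries, thinned libraries and junctions without zinc finger and histone genes were chosen only after the result was seen. No paired analysis was possible because each time point was 1 library with no pairing named in the labels. Where a setting changed a value, the cause was not tested unless the scaling itself shifts every slope.

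With ribosomal protein mRNAs as reference 7766 genes fell and 63 rose, and with respiratory chain mRNAs 6849 and 70. Library size gave 3986 and 1174, upper quartile 3132 and 3387, the IVT entries 9454 and 68. No minimum count gave 3887 and 2248, the stricter minimum 2497 and 2136, robust quasi-likelihood 3407 and 2613, DESeq2 3219 and 2397, limma-voom 3624 and 2796, and thinning 3345 and 2349. Leaving out 1 library gave 2049 to 3485 falling and 699 to 2805 rising. Curved genes numbered 601 with the stricter minimum, 246 with DESeq2 and 675 with the IVT entries. Lists passing directional fry numbered 9 in the main form, 5 with library size, 15 with upper quartile and 16 with the stricter minimum. They numbered 20 with limma-voom, 20 with the IVT entries and 0 to 1 with a library left out, where fewer residual degrees of freedom remained. Camera, a different test, passed 18 lists with the preset correlation and 0 with an estimated one. The latter form rests on 2 residual degrees of freedom, so its failures do not show that correlation between members undoes a list. For glycolysis the estimated correlation, -0.0281, was below the preset 0.01. Yet camera's adjusted p there went from 0.00192 to 0.424. Fry takes nothing from DESeq2 or the robust fit, which gave no value.

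Fold counts at 2, 4 and 6 h changed as follows. With ribosomal protein mRNAs 913, 2511 and 3591 genes were at or below 0.5 and 69 and 56 at or above 2 after 4 and 6 h. With respiratory chain mRNAs these were 881, 2477, 3276, 69 and 60, and with the IVT entries 2744 and 4324 (4 and 6 h) and 64 and 49. Without a minimum 1047 genes were at or below 0.5 at 2 h and 344, 543 and 605 at or above 2. The stricter minimum gave 242, 770 and 1079, and 7, 18 and 25.

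The half-life of the typical gene was 11.6 h with respiratory chain mRNAs, 10.0 h with the 95th percentile of slopes, 53 h with library size, 7.99 h with the IVT entries and 9.69 to 12.5 h with a library left out. No half-life came out with the mitochondrially encoded mRNAs as reference (slope difference 0.065). None came out with the typical transcript (0.0017), where the scaling fixed this in advance. The junction rho was 0.479 without zinc finger and histone genes.

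List medians that changed sign were, with ribosomal protein mRNAs, respiratory chain -0.0068, mitochondrial ribosomal proteins -0.084, glycolysis -0.027, proteasome -0.028, translation factors -0.036, S phase -0.081, snoRNA hosts -0.029, nuclear RNAs -0.064, RNA polymerase III -0.047, fibroblast -0.053, cholesterol -0.054, synthetases -0.045, housekeeping -0.019 and ER-made proteins -0.027. With respiratory chain mRNAs they were mitochondrial ribosomal proteins -0.073, glycolysis -0.016, proteasome -0.017, translation factors -0.025, S phase -0.070, snoRNA hosts -0.017, nuclear RNAs -0.052, RNA polymerase III -0.035, fibroblast -0.043, cholesterol -0.043, synthetases -0.034, housekeeping -0.0083 and ER-made proteins -0.016. With the IVT entries they were ribosomal proteins -0.032, respiratory chain -0.040, mitochondrial ribosomal proteins -0.12, glycolysis -0.060, proteasome -0.061, translation factors -0.069, S phase -0.11, snoRNA hosts -0.060, nuclear RNAs -0.095, RNA polymerase III -0.079, fibroblast -0.083, cholesterol -0.086, synthetases -0.077, housekeeping -0.052 and ER-made proteins -0.060. With library size they were S phase -0.0066 and mitochondrial ribosomal proteins -0.010, and with upper quartile RNA decay 0.0046 and primitive endoderm 0.013. With the stricter minimum they were heat shock 0.025, mitochondrial ribosomal proteins -0.0012, D-type cyclins 0.044, primitive endoderm 0.00051 and trophectoderm 0.0037. Without 0 h they were heat shock 0.0028, mitochondrial ribosomal proteins -0.015 and primitive endoderm 0.051, which was 0.0024 without 4 h and 0.0041 with thinning.

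Reversed genes with ribosomal protein mRNAs were Lefty2 -0.046, Pgk1 -0.00014, Ldhb -0.00076, Zfp664 -0.019, Zfp277 -0.030, Gins2 -0.033, Cenpa -0.010, Ccnb2 -0.033, Ccnd1 -0.032, Smg5 -0.0039, Cnot10 -0.010, Sparc -0.024, Krt7 -0.0075, Krt8 -0.0091, Tm7sf2 -0.022, Dhcr7 -0.022, Hsp90ab1 -0.0052, Hspe1 -0.013, Gars -0.026, Gapdh -0.023 and Actb -0.019. With respiratory chain mRNAs they were Lefty2 -0.035, Zfp664 -0.0085, Zfp277 -0.019, Gins2 -0.022, Ccnb2 -0.022, Ccnd1 -0.021, Sparc -0.013, Tm7sf2 -0.011, Dhcr7 -0.011, Hspe1 -0.0018, Gars -0.015, Gapdh -0.012 and Actb -0.0081.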

Other observations

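The tests on H1 copies, on the pool for antisense genes, and on nuclear RNA and the pool for Malat1 were chosen only after the result was seen. Replication-dependent histone mRNAs fell most steeply and on the main scale stopped falling by 4 h. Their median change from 4 to 6 h was 0.18 log2 units, against 0.16 for ribosomal protein mRNAs. The IVT entries rose from 6457 to 7748 CPM in that interval, so whether a small fall remained depends on the scale. The slowing does not. From 2 to 4 h the histone median change was -1.25 on the main scale, and it stays far larger in size than the later one against either reference. A floor of background reads could end a loss in this way. Against 33 histone genes, other genes matched on loss and level at 4 h (a median of 11 per histone gene) showed less recovery, with a difference of 0.389 log2 units from 4 to 6 h (bootstrap 95% interval 0.316 to 0.487). The histone genes moved together (estimated correlation 0.99) across 1 pair of libraries, so the interval is too narrow and the cause was left open. Reads shared between near-identical copies may blur single genes, yet the 5 linker histone H1 genes had a median slope of -0.645 (lowest -0.894, highest -0.582, all 5 called).

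Of 27 genes antisense to exons and typed long non-coding by the annotation, 9 rose and 6 fell, with a median slope of 0.0038. Of 71 others so typed 14 rose and 11 fell, with a median of 0.013. The 9 include Cct6a (847 CPM at 0 h, slope 0.067), a chaperonin subunit gene, so the set is not purely non-coding. The 9 had a median slope of 0.179 (bootstrap 95% interval 0.0716 to 0.395) and the IVT entries 0.127, but the 9 were chosen for rising, so this says nothing about a shrinking pool. Wrong-strand reads could add to antisense genes, but the 27 and the 71 differed by -0.00953 in median slope (bootstrap 95% interval -0.0699 to 0.076, permutation p = 0.824). Reads of genomic DNA were looked for in 1457 olfactory and vomeronasal receptor genes. At 6 h these reached 1.98 times their summed 0 h level (exact 95% interval 1.7 to 2.29, counting error only). The IVT entries also rose, from 4636 to 7748 CPM. A constant background would gain share if the RNA pool shrank, so the rise does not show DNA added late. None of the 3 was settled.

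Malat1 and mt-Rnr2 rose about 3-fold between 0 and 2 h. More nuclear RNA in the treated libraries could lift Malat1. The 10 other nuclear-retained RNAs had a median change of -0.125 log2 units (bootstrap 95% interval -0.984 to 0.354) and Rn7sk one of -0.025. The 10 ranged from -1.87 for Mir17hg to 0.805 for Meg3. Their median mixes loss of these RNAs with any such gain, and Rn7sk is 1 RNA, so this was left open. The smaller of the 2 changes exceeded that of the IVT entries by 1.28 (changes of 1.44 for mt-Rnr2, 1.62 for Malat1 and 0.151 for the entries). Both RNAs were named for their steep rise and the nature of the entries is not known, so the part of a shrinking pool was left open. Ribosomal RNA was depleted from these libraries, and how far this moved mt-Rnr2 was not tested.

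Slopes went with gene features across coding genes, which are not independent. ATTTA pentamers in the 3' UTR went with faster loss (Spearman rho -0.109 over 10267 genes, permutation p = 1e-04, the smallest possible, partial rho -0.104), as did longer 3' UTRs (-0.151, partial -0.142, permutation p = 1e-04). More exon junctions per kb went with slower loss (0.516 over 10966 genes, partial 0.456, permutation p = 1e-04). Transcript GC content showed no monotone relation with slope by itself, with rho 0.00947 (permutation p = 0.325). The partial rho was 0.0944, near the size of the ATTTA one. A rank correlation can miss a relation that is not monotone, so a GC bias between libraries was not excluded. For falling and for rising genes, 1 of the 12 orders of the time points, the true one, reached the observed number of calls, and the highest count in any other order was 0. With 12 orders a share under 0.05 cannot be reached.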
